A study of Homo sapiens with 27 samples.

How the data were processed

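The series holds 27 libraries in 9 groups of 3, named here by gene set, growth factor and DOX timing as GEO's labels give them. The libraries of the NFATC2 set carry the numbers 48, 49 and 53 in their names and those of the CREB5 set 54, 58 and 59; they are called libraries 1, 2 and 3 of each group. The labels of the 6 vehicle samples of the NFATC2 set do not mention NFATC2 and were placed in that set by their numbers. Whether replicates came from separate cultures is not stated, so the p-values measure the spread between samples. No library with DOX and without an induced gene is among the samples analysed here.

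The signal values were deposited as normalized counts in 3 tables, per the file names. Their low values are whole multiples of 1 step per library (100% of values within 0.1 of a whole multiple). Division of whole counts by a size factor for each library would give this. The steps were 0.9015 to 0.9924 in the BMP4 table of the NFATC2 set and 0.8365 to 1.2023 in the CREB5 set. The whole counts may have been adjusted before that division, so they need not be the reads as first counted. Dividing by the step gave the recovered reads used for depth and for 2 of the alternatives. The submitters' processing notes name Salmon 1.2.1, Salmon 1.8.0, DESeq2 1.38.0 and hg38, with no role or order. The annotation, the use of strand, any filter and any batch adjustment are not given in the sources used here. The log2 fold changes of the NFATC2 set vehicle comparison were deposited by the authors, per the file headers, and are given here as TGF-beta minus BMP4, the sign having been checked against the group means in the same table. The p-value column deposited with them is the authors' adjusted p, whose highest value was 0.04998, so that table holds only genes past a threshold.

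The CREB5 table had 21026 lines for 20390 gene IDs and the BMP4 table of the NFATC2 set 21477 lines for 20811 gene IDs. Repeated IDs had identical values and were kept as 1 gene, and each ID had a symbol in the gene name table. The table of vehicle libraries of the NFATC2 set holds 6632 genes, and its recovered reads (14.3 to 17.4 M) cover those genes only. In that table the replicates of a group differed far less than counting noise allows: the median variance was 0.067 (BMP4) and 0.0568 (TGF-beta) of the counting variance, against 0.693 for counting noise alone, and the median SD of log2 values was 0.0126. Each group was therefore counted as 1 sample, no test was run on it, and the planned count of genes changed between TGF-beta and BMP4 vehicle in the NFATC2 set was replaced by the authors' own values. The same 3 BMP4 vehicle libraries appear in both tables of the NFATC2 set, where the SD of their log2 difference was 0.372 to 0.435 and 5.8 to 8.2% of genes lay over 1.5-fold apart. In the BMP4 table, 3 columns of early DOX libraries match no sample and were not used. Tables were normalized separately, so each test stayed within 1 table.

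Genes with a normalized count of at least 10 in at least 3 libraries of a fit were tested, 14397 in the NFATC2 fit (6 libraries, 4 residual degrees of freedom) and 15361 in the CREB5 fit (18 libraries, 12 residual degrees of freedom). Values were transformed to log2(normalized count + 1) and tested with limma 3.58.1 (lmFit with a mean per group, eBayes with trend), 2-sided, with Benjamini-Hochberg adjustment over the genes of each of 10 contrasts and a threshold of 0.05. The 18 libraries of the CREB5 set were fitted together so that the 6 groups share 1 estimate of the spread, and the replicate number was not a term. The contrasts were mid DOX against vehicle in the NFATC2 set, TGF-beta against BMP4 vehicle in the CREB5 set, early and mid DOX against vehicle in each arm, mid against early DOX in each arm, and the difference of the early and of the mid effect between arms. The comparisons, tests, thresholds, gene lists and the rule for named genes were fixed before the data were examined.

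The text names genes by this rule: NFATC2, CREB5, PRG4, COL10A1, COL2A1, ACAN and SOX9 in every contrast; per contrast the 8 largest rises and 8 largest falls past 0.05 with a mean of at least 100 in the higher group and no overlap between the libraries of the 2 groups (4 each way and no overlap rule for differences between arms), among genes with a symbol; and per gene list up to 4 members past 0.05 with the largest change or, where none passed, 2 with the highest mean. Some genes that this rule names are not reported here. Groups of 3 against 3 do not overlap in 10% of genes by chance. The genes named for mid against early DOX in TGF-beta and those given for overlaps between comparisons were chosen after their values were seen. For genes with a group listed at 0, and for genes whose group holds 1 to 3 reads in all, no fold is given; a value called fitted for such a gene depends on the pseudocount and is not a fold. Reads of paralogs (PRB1 and PRB2, ORM1 and ORM2, CD24) and of readthrough or antisense genes are uncertain.

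The 24 gene lists cover articular, hypertrophic, cartilage matrix, fibroblast and tendon, and osteoblast genes, targets of TGF-beta, BMP, NFAT and CREB, proliferation, catabolic and inflammatory, WNT, hedgehog, interferon, integrated stress response (called stress response), mitochondrially encoded, immediate-early and hypoxia genes, and markers of neural, endothelial and blood, muscle, epithelial, pluripotent and adipocyte cells. Some genes stand in more than 1 list, for example PTGS2 and the NR4A genes. Each list was tested with camera (limma) with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a contrast, and members were also adjusted over the list alone. Of 63 list calls over the 10 contrasts, 8 held with an estimated correlation: BMP targets in TGF-beta against BMP4 vehicle and in both differences between arms, proliferation genes with mid DOX in TGF-beta, with mid against early DOX in TGF-beta and in the mid difference between arms, catabolic genes with mid against early DOX in TGF-beta, and hypoxia genes with mid against early DOX in BMP4. A fry test of each list was run too and is not described here.

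A signature held the genes past 0.05 and over 2-fold apart between TGF-beta and BMP4 vehicle in 1 gene set and was tested with camera in the other gene set. The value is the mean log2FC of its genes minus that of the other tested genes. Signature tests of the difference between arms were added after the signatures in each arm had been seen. Overlaps of calls are given beside the number for independent lists (calls of 1 comparison times calls of the other over the genes tested in both).

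The scripts were tested on simulated counts with known changes. With limma, 62.5% of 2-fold and 83.3% of 4-fold changes were recovered for NFATC2 mid DOX (14200 genes, 12 false among 152 calls), 18.6% and 63.3% for CREB5 mid DOX in BMP4 (15094 genes, 5 false among 85) and 7% and 42.9% for the mid difference between arms (15105 genes, 4 false among 53). With no gene changed, limma made 0, 1 and 0 calls. With DESeq2 the false calls were 53 of 211, 24 of 137 and 30 of 103, and with no gene changed 5, 8 and 7. Alternatives were a pseudocount of 8, no filter, a mean of at least 50, quantile normalization, a replicate block, a fit of only the groups compared, and each library left out in turn; edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, and a block within each arm, were added after the data were seen. No scaling moved the median of all genes by over 0.1 log2. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.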

Results

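The transcriptomes of chondrocytes, the cells of cartilage, were measured after derivation in vitro from H9, an established human embryonic stem cell line. PolyA RNA was sequenced after collagenase digestion. The cultures had been grown in 1 of 2 growth factor arms, BMP4 or TGF-beta, and received doxycycline (DOX), a drug widely used to switch on engineered genes, or vehicle. The series title refers to overexpression of transcription factors and its design text to modulation of NFATC2 or CREB5. The 27 libraries formed 9 groups of 3. The NFATC2 set held BMP4 vehicle, TGF-beta vehicle and BMP4 with mid DOX, and the CREB5 set held vehicle, early DOX and mid DOX in each arm. Library depth, recovered as whole reads, was 22.1 to 24.0 M for the NFATC2 set in BMP4, 20.1 to 23.6 M for the CREB5 set in BMP4 and 16.8 to 22.0 M for the CREB5 set in TGF-beta. Below, levels are normalized counts as mean ± SD (n = 3), fold changes are log2FC ± SE on the log2(normalized count + 1) scale, and adjusted p comes from limma with Benjamini-Hochberg adjustment. For a gene list, the p given first is the adjusted p of the set test camera with a preset correlation.

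Replicates varied more in the CREB5 set than in the NFATC2 set. The median variance between replicates of a group was 16 to 28.7 times the counting variance in the CREB5 set and 3.80 to 4.67 times in the BMP4 groups of the NFATC2 set, where counting noise alone gives 0.693. In the TGF-beta arm of the CREB5 set, 3 libraries had a lower mean correlation with their own group than with another group: early DOX library 2 (0.941 against 0.947), mid DOX library 1 (0.935 against 0.939) and vehicle library 3 (0.934 against 0.939). In the CREB5 set, deviations from the group means largely cancelled over the 6 libraries that share a replicate number: the variance of their sum was 0.122 of the sum of their variances, averaged over the 3 numbers (10957 genes). In the NFATC2 set in BMP4, deviations of same-numbered mid DOX and vehicle libraries were also opposed, with correlations of -0.251, -0.468 and -0.476. COL2A1, which encodes the main collagen of cartilage, alone held 3.08 to 15.0% of the counts in BMP4 libraries of the CREB5 set and 0.156 to 1.41% in its TGF-beta libraries.

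The induced genes were examined first. NFATC2, a transcription factor activated by calcineurin, stood at 1246 ± 95.9 normalized counts in vehicle and 20990 ± 472 with mid DOX in the NFATC2 set in BMP4, a log2FC of 4.08 ± 0.065 (adjusted p = 6.4e-07). CREB5, a transcription factor of the CREB/ATF family, rose with DOX in each of the 4 comparisons of its own set. In BMP4 it stood at 181 ± 27.8 in vehicle, 983 ± 67.8 with early DOX (log2FC 2.45 ± 0.23, adjusted p = 3.2e-05) and 2292 ± 605 with mid DOX (3.64 ± 0.23, adjusted p = 8.2e-08). In TGF-beta it stood at 260 ± 35.4 in vehicle, 3335 ± 820 with early DOX (3.65 ± 0.23, adjusted p = 7.7e-08) and 3028 ± 838 with mid DOX (3.51 ± 0.23, adjusted p = 1.4e-07). These 5 calls held under every alternative tried.

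**Figure D1:**
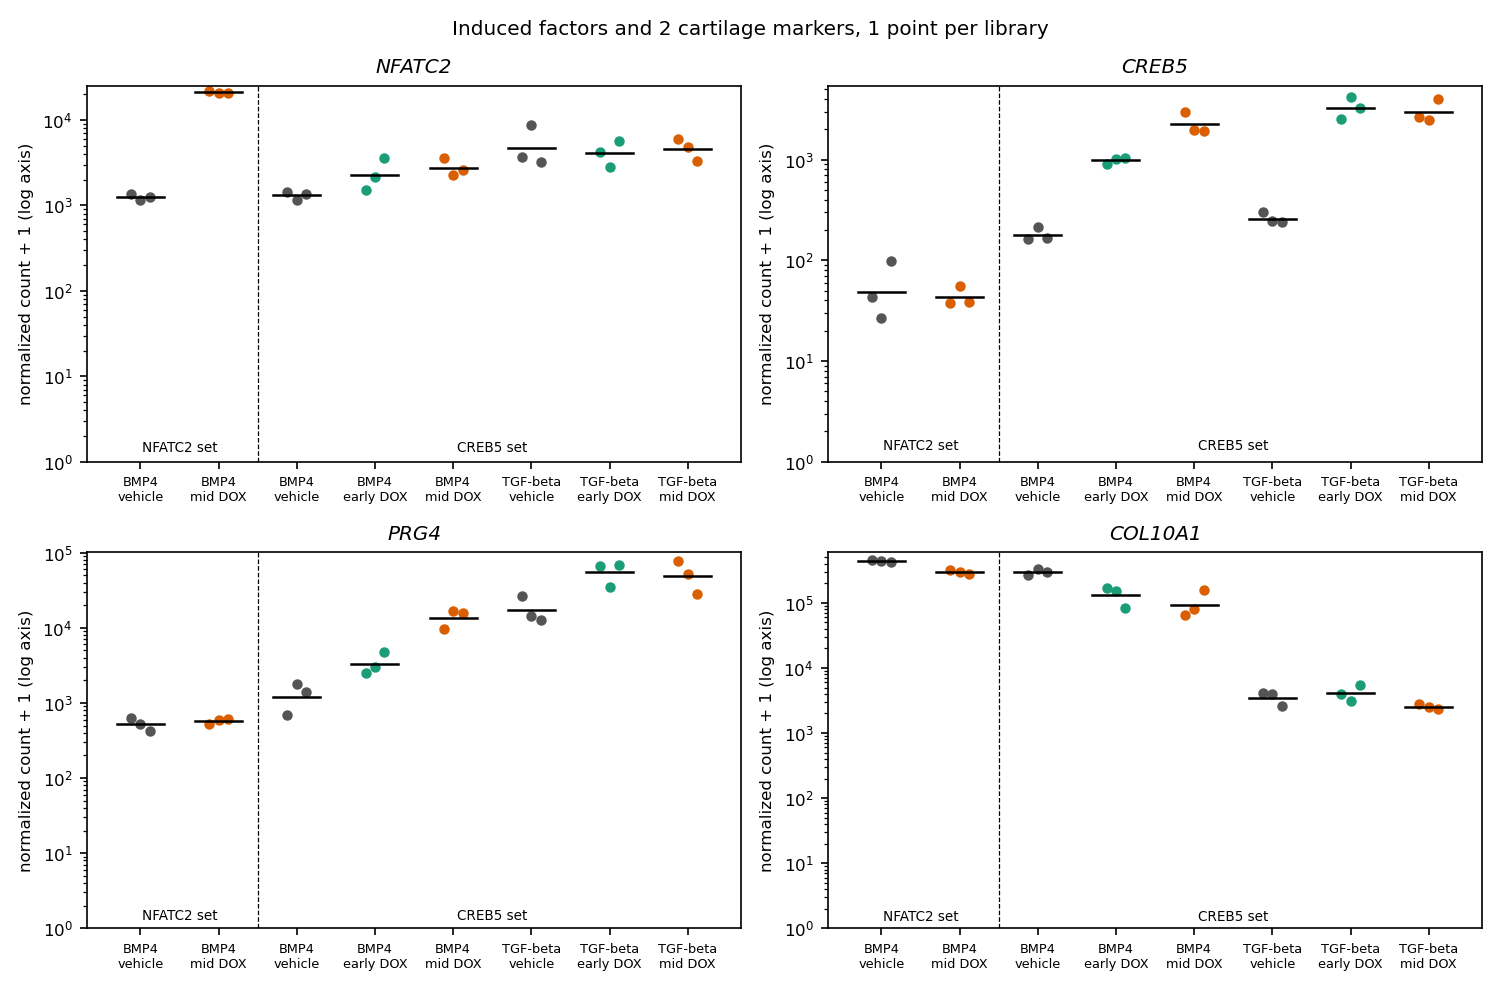
Normalized count + 1 on a log axis for NFATC2, CREB5, PRG4 and COL10A1, with 1 point per library and a line at the mean of the log values for each of 8 groups (2 of the NFATC2 set in BMP4 and 6 of the CREB5 set; the 2 sets were normalized separately). PRG4 lies near 1294 in BMP4 vehicle of the CREB5 set, near 14040 with mid DOX there and near 17990 in TGF-beta vehicle, while COL10A1 has the opposite order.

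How TGF-beta chondrocytes differ from BMP4 chondrocytes without DOX was asked first in the NFATC2 set, for which the authors' deposited table holds their own comparison of 6632 genes, 3380 higher in TGF-beta and 3252 higher in BMP4 (2065 and 1713 over 2-fold). In the authors' deposited table, PRG4, which encodes the joint lubricant lubricin, had a mean of 50820 in TGF-beta and 509 in BMP4 (log2FC 6.63), and COL10A1, the collagen of hypertrophic cartilage, had 3208 and 349400 (-6.76). By the authors' deposited table, NFATC2 (2.51) and CREB5 (1.10) were also higher in TGF-beta, while COL2A1 (-3.53), ACAN, which encodes aggrecan (-1.83), and the chondrocyte transcription factor SOX9 (-1.21) were higher in BMP4. The largest TGF-beta-high values in the authors' deposited table belonged to genes at or near 0 in BMP4. By the authors' deposited table DOC2B (1240) and VASN (448) were listed at 0 in BMP4, and TRIM27, KCNMB2, OLFM2, OLFML2B, ARHGAP11A and NCEH1 had means of 305 to 1004 in TGF-beta and of 0.30 to 0.614 in BMP4. The largest BMP4-high values in the authors' deposited table were those of PRB2 (5640 in BMP4 and 0.734 in TGF-beta), PRB1, SCNN1B, the gel-forming mucin MUC5AC (-9.04), IL17B (-9.0), the chemokine CXCL13 (-8.88), PANX3 (-8.72) and IBSP (-8.64). Replicates in that table differed by less than sampling noise (variance 0.067 and 0.0568 of the counting variance), so each group counted as 1 sample, untested.

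Of the gene lists fixed in advance, the authors' deposited table placed 10 articular genes higher in TGF-beta and 1 higher in BMP4, among them CILP2 (5.59) and PRG4. In the authors' deposited table hypertrophic genes were split 2 and 14 (PANX3, IBSP), cartilage matrix genes 3 and 18 (COMP 6.09 against SNORC -6.78). Fibroblast and tendon genes were split 14 and 3 (TNMD 7.12), and osteoblast genes 1 and 5 (SP7 -8.33) in the authors' deposited table. The authors' deposited table split TGF-beta targets 11 and 2 (LTBP2 5.73, LTBP1 5.63) and BMP targets 1 and 8 (ATOH8 -4.35, NOG -3.11). The authors' deposited table split NFAT targets 7 and 1, CREB targets 5 and 3, catabolic and inflammatory genes 10 and 2, WNT genes 6 and 3, immediate-early genes 7 and 0, hypoxia genes 5 and 4 and proliferation genes 1 and 4. The remaining lists held 0 to 5 genes of the authors' deposited table each. In the authors' deposited table hedgehog genes were split 3 and 2, interferon 1 and 2, stress response 2 and 3, and neural 0 and 1. The others in the authors' deposited table were endothelial and blood 4 and 1, muscle 1 and 2, epithelial 0 and 1, pluripotent 1 and 0, adipocyte 0 and 1, and mitochondrially encoded 0 and 0. The authors' deposited table holds only genes past the authors' own threshold (highest adjusted p 0.05), so a gene missing from it was not counted.

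The same question was tested in the CREB5 set, where the TGF-beta vehicle libraries again had high PRG4 and low COL10A1. PRG4 was 17990 ± 7675 in TGF-beta and 1294 ± 560 in BMP4 (log2FC 3.82 ± 0.43, adjusted p = 5.7e-06). COL10A1 was 3567 ± 816 and 300600 ± 31520 (-6.42 ± 0.33, adjusted p = 7.2e-10). In total 3918 of 15361 genes passed, 1814 higher in TGF-beta and 2104 higher in BMP4, of which 1080 and 1520 differed over 2-fold. The growth factor gene FGF2 was 2035 ± 871 in TGF-beta and 20.54, 19.72 and 0 in the BMP4 libraries (7.95 ± 0.88). Other genes much higher in TGF-beta were COL15A1 (6.12 ± 0.48), COL22A1 (6.45 ± 1.05), FGF1 (5.77 ± 0.74) and FAP, a serine protease of activated fibroblasts (5.75 ± 0.39). PHLDA2 was higher too (adjusted p = 0.00912), with 352, 663 and 532 in TGF-beta against 6.85, 0 and 0 in BMP4. The genes most strongly higher in BMP4 were PRB2 and PRB1, near-identical salivary protein genes whose reads cannot be assigned with certainty (-11.09 ± 1.05 and -10.11 ± 1.32). They were followed by MUC5AC (-9.17 ± 0.66), CXCL13 (-9.15 ± 0.29, adjusted p = 6.2e-12), IBSP (-8.22 ± 0.61), the histamine synthesis enzyme HDC (-8.20 ± 0.41), CD24 (-8.15 ± 0.36) and the sodium-calcium exchanger SLC8A3 (-8.08 ± 0.91). NFATC2 (1.84 ± 0.37, adjusted p = 0.00142) was higher in TGF-beta, COL2A1 (-4.45 ± 0.84) and ACAN (-2.57 ± 0.63) were lower, and CREB5 (0.53 ± 0.23, adjusted p = 0.0984) and SOX9 (-0.26 ± 0.27, adjusted p = 0.526) did not pass. Of 83 named genes that passed, 70 kept the call under every alternative and 10 lost it without some library. The losses were 5 without BMP4 vehicle library 1, 5 without BMP4 vehicle library 3, 2 without TGF-beta vehicle library 1, and 4 each without libraries 2 and 3 of that group.

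By list, 11 of 15 articular genes were higher in TGF-beta and 1, TNC, was lower, with CILP (5.50 ± 0.99) and CILP2 (3.28 ± 0.41) leading (camera adjusted p = 1.1e-05, adjusted p = 0.101 with an estimated correlation). Of 17 hypertrophic genes 15 were lower, including PANX3 (-7.66), ALPL (-7.40) and the hedgehog ligand IHH (-6.84), and VEGFA was higher (1.8e-13, adjusted p = 0.12 with an estimated correlation). Of 21 cartilage matrix genes 17 were lower, such as SNORC (-5.93) and COL9A1 (-4.89), and COMP, a matrix protein abundant in tendon and articular cartilage, was higher (5.72 ± 0.40) (2.2e-06, adjusted p = 0.229 with an estimated correlation). Fibroblast and tendon genes had 12 of 17 higher (TNMD 5.11, THY1 4.69, SCX 3.97) and DCN and LUM lower (1.1e-05, adjusted p = 0.206 with an estimated correlation). Osteoblast genes had 4 of 7 lower (DLX5 -3.60) (0.00682, adjusted p = 0.206 with an estimated correlation). Targets of TGF-beta had 9 of 15 higher (LTBP1 3.68) and SMAD7 and CCN2 lower (0.0013, adjusted p = 0.408 with an estimated correlation). Targets of BMP had 10 of 12 lower (NOG -4.08, ATOH8 -3.97, BAMBI -2.57) and MSX2 higher (7.2e-08, adjusted p = 0.02 with an estimated correlation). Catabolic and inflammatory genes had 7 of 18 higher (MMP3 3.60, CXCL1 3.52) and TNFAIP3 and MMP13 lower (0.00263, adjusted p = 0.226 with an estimated correlation). These counts were the same adjusted over the list alone, except for 3 lower fibroblast genes and 5 lower osteoblast genes.

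Among the lists that did not pass camera in that comparison, 1 of 11 NFAT targets was higher (PTGS2, the prostaglandin synthesis enzyme, 1.87) and 2 were lower (EGR3 -2.59, NR4A3 -1.46). Of 13 CREB targets 3 were lower (PDE4B -2.23), as were 3 of 20 proliferation genes (MKI67 -2.43, RRM2 -2.31, TOP2A -1.0). Of 13 WNT genes 4 were lower and 1 higher (FRZB -5.00, DKK3 2.45), and 2 of 6 hedgehog genes were lower (IHH, PTCH1 -1.59). Interferon genes had 1 of 12 higher and 2 lower (IRF7 1.22, OAS2 -1.13) and stress response genes 2 of 12 higher (ATF3 0.83, ATF5 0.81). Immediate-early genes had 2 of 12 higher (HSPH1 0.89, ATF3) and hypoxia genes 4 of 11 higher and 2 lower (CA9 4.58, ENO2 2.66, SLC2A1 -1.06). Among markers of other cell types, 2 of 10 endothelial and blood genes (CLDN5, CDH5), 1 of 9 muscle genes (ACTC1 -5.19), 2 of 8 epithelial genes (KRT19 -2.61, KRT8 -0.94) and 3 of 6 adipocyte genes (LPL -5.23) were lower in TGF-beta. Of 7 neural genes 2 were lower (NES -2.05) and TUBB3 (1.53) was higher. None of 6 pluripotency genes passed with limma, edgeR or DESeq2, and 1 had an unadjusted p under 0.05. Counts adjusted over the list alone were the same except for 3 lower hedgehog, interferon, hypoxia and neural genes and 1 higher gene each for stress response and immediate-early genes. None of the 13 mitochondrially encoded genes could be tested in any comparison.

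What NFATC2 induction does in BMP4 chondrocytes was asked by comparing mid DOX with vehicle in the NFATC2 set. TNN, an extracellular matrix glycoprotein of the tenascin family, had the largest rise of the named genes, from 22.2 ± 13.1 to 1314 ± 13.7 (log2FC 5.97 ± 0.35, adjusted p = 3.9e-04). RCAN1, an inhibitor of calcineurin and a classic NFAT target, rose from 2122 ± 79.0 to 7988 ± 362 (1.91 ± 0.056, adjusted p = 1.6e-05). COL10A1 was lower, 300700 ± 23580 against 439300 ± 14510 (-0.55 ± 0.084, adjusted p = 0.0147), whereas PRG4 did not pass, with 577 ± 45.8 against 525 ± 99.7 (0.15 ± 0.15, adjusted p = 0.64). In total 802 of 14397 genes passed, 479 higher and 323 lower, of which 145 and 27 changed over 2-fold (196 with a replicate block, 1482 with DESeq2). The other large rises were FBXL17 (4.5 ± 0.65), TSPAN2 (3.40 ± 0.094), USH1C (3.30 ± 0.25), the cyclooxygenase PTGS1 (3.00 ± 0.19), the coenzyme Q synthesis enzyme COQ2 (2.71 ± 0.55) and RELB, a subunit of NF-kB (2.58 ± 0.57). The large falls were CHCHD5 (-2.56 ± 0.25), the lysosomal cholesterol carrier NPC2 (-2.10 ± 0.37), EVI5 (-1.42 ± 0.20), KYAT1 (-1.40 ± 0.18), LRP12 (-1.38 ± 0.30) and RNF111 (-1.05 ± 0.11). Others were the antisense gene SLC44A3-AS1 (-1.41 ± 0.31) and the readthrough gene DUS4L-BCAP29 (-1.09 ± 0.23). The last 2 overlap other genes, so their reads are uncertain. CREB5 (-0.18 ± 0.48, adjusted p = 0.891), COL2A1 (-0.21 ± 0.13, adjusted p = 0.399), ACAN (0.12 ± 0.11, adjusted p = 0.617) and SOX9 (-0.11 ± 0.065, adjusted p = 0.393) did not pass. COL2A1 passed with DESeq2 (adjusted p = 0.0422, range 0.0422 to 1 over the alternatives).

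Of 10 NFAT targets 8 rose, among them PTGS2 (2.15 ± 0.11), RCAN1, EGR2 (1.91 ± 0.091) and the cytokine LIF (1.53 ± 0.16), and none fell (camera adjusted p = 1.8e-13, adjusted p = 0.103 with an estimated correlation). Catabolic and inflammatory genes had 8 of 16 up, including CCL2 (2.03 ± 0.15) and the mitochondrial superoxide dismutase SOD2 (1.63 ± 0.16) (9.1e-13, adjusted p = 0.103 with an estimated correlation). Immediate-early genes had 5 of 11 up (ZFP36 0.85, JUN 0.46) and CREB targets 3 of 13 (NR4A2 0.99, NR4A1 0.93, NR4A3 0.74). WNT genes had 4 of 12 up (SFRP1 1.09, AXIN2 0.94) and FRZB down. The camera adjusted p of these 3 lists was 2.2e-06, 9.2e-04 and 9.2e-04. Each had adjusted p = 0.103 with an estimated correlation. Articular genes had 3 of 15 up (CILP2 1.32 ± 0.063, TNC 1.01, ASPN 0.55; 0.00355, adjusted p = 0.236 with an estimated correlation). Fibroblast and tendon genes had 4 of 17 up (COL1A1 0.72, FN1 0.62; 0.00564, adjusted p = 0.259 with an estimated correlation). TGF-beta targets had 2 of 14 up (BHLHE40 0.47, LTBP2 0.36; 0.00355, adjusted p = 0.409 with an estimated correlation). Hypertrophic genes had 6 of 17 down, including IBSP (-0.55 ± 0.060), COL10A1, RUNX2 (-0.42) and MEF2C (-0.39) (3.0e-06, adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone, 8 NFAT, 12 catabolic, 7 immediate-early, 5 CREB, 5 articular, 6 fibroblast, 5 TGF-beta target and 6 WNT genes rose and 11 hypertrophic genes fell.

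In the other lists of that comparison, cartilage matrix genes had 2 of 21 up and 2 down (COMP 1.00, CNMD 0.82, COL11A2 -0.42, SNORC -0.29) and BMP targets 2 of 13 up and 1 down (BAMBI 0.55, ID4 0.34, ID2 -0.26). Stress response genes had 1 up and 1 down (ATF3 0.44, SLC7A11 -0.44). GLI1 (1.25), IFI6 (1.5), PTPRC (0.91) and KRT19 (0.61) were the members up in the hedgehog, interferon, endothelial and blood, and epithelial lists. SLC2A1 (-0.38), a glucose transporter, was the hypoxia gene down. With limma none of the osteoblast (6 tested), proliferation (20), neural (5), muscle (8), pluripotent (8) and adipocyte (5) genes passed. At an unadjusted p under 0.05 these lists held 1, 3, 1, 2, 0 and 1 genes, edgeR called 0 in each, and DESeq2 called 3 proliferation genes, 1 muscle gene and 0 in the others. The count of 802 moved to 339 without mid DOX library 2, 381 without mid DOX library 3, 246 without vehicle library 2 and 270 without vehicle library 3. In all, 30 of 59 named genes lost their call without some library (13 to 27 per library left out). COL10A1 lost its call with quantile normalization, where its log2FC was -0.255 (adjusted p = 0.202, range 2.3e-15 to 0.202 over the alternatives). With no filter it lost the call at an unchanged log2FC of -0.549 (0.0562). It also lost it without mid DOX library 2 (0.073), mid DOX library 3 (0.0724) or vehicle library 2 (0.0843).

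What CREB5 induction does in BMP4 chondrocytes was asked with early and with mid DOX, each against the same vehicle libraries. With mid DOX, PRG4 rose to 14040 ± 3941 from 1294 ± 560 in vehicle (log2FC 3.5 ± 0.43, adjusted p = 1.4e-04), a call kept under every alternative. COL10A1 fell to 101300 ± 51050 from 300600 ± 31520 (-1.68 ± 0.33, adjusted p = 0.0093). ODAM, a protein of tooth enamel epithelium, rose to 2040 ± 232 from 32.6 ± 7.44 (5.94 ± 0.28, adjusted p = 3.2e-09), and FGF2 reached 887 ± 173 against 20.54, 19.72 and 0 (6.84 ± 0.88). In total 349 of 15361 genes passed, 249 higher and 100 lower (218 and 71 over 2-fold), against 179 with a replicate block and 708 with DESeq2. The other large rises were CGA, the shared subunit of glycoprotein hormones (6.54 ± 0.47), CHODL (6.27 ± 0.43), the phosphatase PTPRQ (6.01 ± 0.57) and FGF10 (5.90 ± 0.53). Also up were VGLL2 (138 ± 51.4 against 0, 2.19 and 0) and the fatty acid transporter family gene SLC27A3 (4532, 5497 and 355 against 24.5, 99.7 and 0). The largest falls were PRB1 (-5.31 ± 1.32), PRB2 (-5.05 ± 1.05), MUC5AC (-3.92 ± 0.66), IBSP (-3.74 ± 0.61, adjusted p = 0.00214) and SBK1 (-3.28 ± 0.61). They were followed by MAFA (-2.57 ± 0.64), IHH (-2.36 ± 0.45, adjusted p = 0.00785) and SHROOM2 (-2.33 ± 0.52). NFATC2 (1.08 ± 0.37, adjusted p = 0.17), COL2A1 (-0.62 ± 0.84, adjusted p = 0.839), ACAN (-0.55 ± 0.63, adjusted p = 0.798) and SOX9 (-0.40 ± 0.27, adjusted p = 0.594) did not pass. NFATC2 passed when only the 2 groups compared were fitted (adjusted p = 0.0338, range 0.0338 to 0.441 over the alternatives).

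With mid DOX in BMP4, 4 of 15 articular genes rose, PRG4, THBS4 (3.43), TPPP3 (3.36) and TNC (1.60) (camera adjusted p = 1.5e-04, adjusted p = 0.151 with an estimated correlation). Of 17 hypertrophic genes 3 fell, IBSP, IHH and COL10A1 (1.6e-07, adjusted p = 0.19 with an estimated correlation). Fibroblast and tendon genes had 3 of 17 up (THY1 2.01, FAP 1.63, PRRX1 0.94; 8.4e-04, adjusted p = 0.263 with an estimated correlation). Catabolic genes had 3 of 18 up (the aggrecanase ADAMTS5 2.42, CXCL1 1.68, PTGS2 1.57; 0.00924, adjusted p = 0.263 with an estimated correlation). Interferon genes had 1 of 12 up (IFI44L 2.70; 2.3e-05, adjusted p = 0.19 with an estimated correlation). Hypoxia genes had 3 of 11 down (ADM -1.22, SLC2A1 -1.03, BNIP3 -0.86; 6.0e-05, adjusted p = 0.151 with an estimated correlation). Stress response genes had 2 of 12 down (DDIT4 -1.89, VLDLR -1.09; 0.00551, adjusted p = 0.335 with an estimated correlation). BMP targets had 2 of 12 down (ATOH8 -1.08, ID2 -0.90; 0.00798, adjusted p = 0.19 with an estimated correlation). Adipocyte genes had 1 of 6 up (PPARG 1.25; 0.00551, adjusted p = 0.151 with an estimated correlation). LTBP1 (1.52), PTGS2, TCF7 (1.32) and TUBB3 (1.52) were the genes up among TGF-beta targets, NFAT targets, WNT genes and neural genes. Adjusted over the list alone, 4 articular, 6 fibroblast, 4 catabolic, 7 interferon and 3 adipocyte genes rose, and 8 hypertrophic, 5 hypoxia, 2 stress response and 2 BMP target genes fell. With limma none of the cartilage matrix (21), osteoblast (7), CREB target (13), proliferation (20), immediate-early (12), endothelial and blood (10), muscle (9), epithelial (8) and pluripotent (6) genes passed. Of these lists 2, 2, 5, 2, 0, 2, 1, 1 and 0 genes had an unadjusted p under 0.05, edgeR called 0 in each, and DESeq2 called 1 cartilage matrix gene, 1 CREB target and 0 in the others. Proliferation genes were lower as a set (camera adjusted p = 0.0302, adjusted p = 0.19 with an estimated correlation).

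The count of 349 moved to 170 without mid DOX library 1, 153 without mid DOX library 2, and 197, 205 and 175 without vehicle libraries 1, 2 and 3. In all, 21 of 40 named genes lost their call without some library (8 to 19 per library left out). COL10A1 lost its call when only the 2 groups compared were fitted (adjusted p = 0.106, range 1.2e-04 to 0.106 over the alternatives) and without mid DOX library 1 (0.0652) or 2 (0.0585). IHH lost it without mid DOX library 1 (0.0587), mid DOX library 2 (0.0574) or vehicle library 3 (0.0574).

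With early DOX in BMP4, ODAM rose to 754 ± 299 (4.44 ± 0.28, adjusted p = 3.1e-07) and PTPRQ to 676 ± 192 (4.93 ± 0.57). MUC5AC fell to 180 ± 57.1 from 3164 ± 1125 (-4.13 ± 0.66, adjusted p = 0.00335). PRG4 was 3427 ± 1233 (1.45 ± 0.43, adjusted p = 0.0936) and COL10A1 136100 ± 45760 (-1.20 ± 0.33, adjusted p = 0.0669), and neither passed. In total 345 genes passed, 163 higher and 182 lower (140 and 125 over 2-fold), against 151 with a replicate block and 799 with DESeq2. Further rises were FGF2 (4.77 ± 0.88), CGA (4.66 ± 0.47), the gluconeogenesis enzyme PCK1 (4.27 ± 0.51), CHODL (3.99 ± 0.43) and GRIP1 (5.38 ± 0.76). FAM83H was listed at 0 in the 3 early DOX libraries and at 281, 289 and 513 in vehicle. Other falls were CLDN5, the endothelial tight junction gene (-5.97 ± 1.11), the paralogs ORM2 and ORM1, whose reads may be shared (-4.00 ± 0.76 and -3.40 ± 0.41), GALNT13 (-3.77 ± 0.69), MAFA (-3.54 ± 0.64) and SH3RF2 (-3.18 ± 0.44). NFATC2 (0.79 ± 0.37, adjusted p = 0.34), COL2A1 (-0.84 ± 0.84, adjusted p = 0.722), ACAN (-0.47 ± 0.63, adjusted p = 0.811) and SOX9 (-0.80 ± 0.27, adjusted p = 0.148) did not pass.

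Among lists in that comparison, fibroblast and tendon genes had 3 of 17 up (THY1 1.77, FAP 1.53, PRRX1 0.69). TPPP3 (2.57), IFI44L (2.11) and the enolase ENO2 (1.64) were the genes up in the articular, interferon and hypoxia lists. Of these 3, camera passed for interferon (4.4e-04, adjusted p = 0.381 with an estimated correlation). ID2 (-1.42) and, of 10 endothelial and blood genes, CLDN5 and CDH5 fell, with camera passing for BMP targets (0.0137, adjusted p = 0.381 with an estimated correlation). None of 17 hypertrophic genes passed, although 1 rose and 10 fell adjusted over the list alone and the list was lower as a set (1.8e-05, adjusted p = 0.381 with an estimated correlation). Cartilage matrix genes were lower as a set (0.0168, adjusted p = 0.564 with an estimated correlation), a call that ended with quantile normalization (0.0641). Adjusted over the list alone 4 articular genes rose and 3 BMP targets fell. With limma 0 genes passed in the lists of hypertrophic, cartilage matrix, TGF-beta target, NFAT target, CREB target, proliferation, catabolic, WNT, hedgehog, stress response, immediate-early, neural, muscle, epithelial, pluripotent and adipocyte genes. At an unadjusted p under 0.05 these held 11, 4, 6, 1, 1, 3, 6, 4, 2, 1, 0, 2, 2, 2, 0 and 1 genes. In each edgeR called 0, and DESeq2 called 5, 2, 3, 0, 0, 1, 1, 1, 2, 0, 0, 1, 1, 1, 0 and 1. The count of 345 moved to 142 without early DOX library 2, 81 without early DOX library 3, and 165, 151 and 123 without vehicle libraries 1, 2 and 3. In all, 12 of 26 named genes lost their call without some library (4 to 12 per library left out). PRG4 passed with DESeq2 (adjusted p = 0.0209, range 0.0209 to 0.354 over the alternatives), with quantile normalization (0.022) and with a replicate block within each arm (0.0246), and not with a block over both arms (0.182). COL10A1 passed with DESeq2 (0.0132, range 0.0132 to 0.468).

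**Figure D2:**
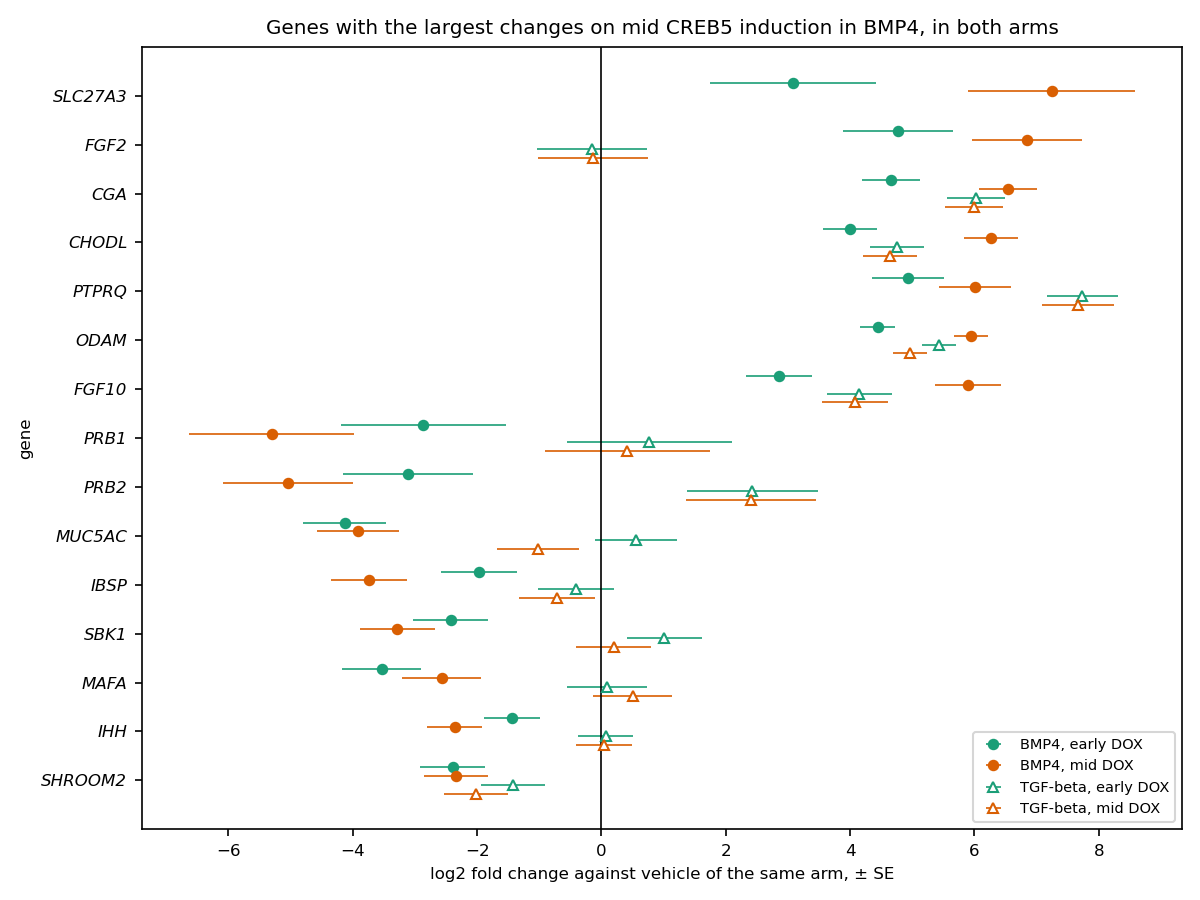
Log2 fold change ± SE (n = 3 libraries per group) against vehicle of the same arm for 15 of the 16 genes with the largest rises and falls with mid DOX in the CREB5 set in BMP4; no value is drawn for comparisons with 3 reads or fewer in a group (VGLL2, and SLC27A3 in TGF-beta). Filled circles are BMP4 and open triangles TGF-beta, with early DOX in green and mid DOX in orange. FGF2 lies at 6.84 with mid DOX in BMP4 and at -0.13 in TGF-beta, while ODAM and PTPRQ are above 0 in all 4 comparisons.

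The same induction in TGF-beta chondrocytes was compared with vehicle of that arm. With early DOX, PTPRQ rose to 1357 ± 277 from 6.72 ± 6.12 (7.74 ± 0.57, adjusted p = 4.6e-07) and PCK1 to 984 ± 532 from 6.73 ± 3.18 (6.90 ± 0.51). With mid DOX ODAM rose to 1956 ± 773 from 59.1 ± 6.07 (4.96 ± 0.28, adjusted p = 5.6e-08). PRG4 was 17990 ± 7675 in vehicle, 57030 ± 18970 with early DOX (1.68 ± 0.43, adjusted p = 0.0638) and 52430 ± 24580 with mid DOX (1.51 ± 0.43, adjusted p = 0.14). COL10A1 was 4181 ± 1209 with early (0.22 ± 0.33, adjusted p = 0.906) and 2557 ± 233 with mid DOX (-0.46 ± 0.33, adjusted p = 0.715). Neither gene passed at either time. Early DOX changed 259 genes, 224 higher and 35 lower (209 and 22 over 2-fold). Mid DOX changed 167 genes, 138 higher and 29 lower (129 and 18 over 2-fold). With a replicate block these counts were 160 and 100, and with DESeq2 472 and 373. The keratin-associated gene KRTAP3-2 was listed at 0 in vehicle and at 195, 337 and 98.2 with early DOX and 152, 257 and 104 with mid DOX. Large early rises were TMEFF2 (6.07 ± 0.54), CGA (6.02 ± 0.47), SLITRK6 (5.70 ± 0.42), the prostaglandin receptor PTGER3 (129 ± 17.7 against 1.08, 1.07 and 0) and VGLL2 (104 ± 38.6 against 1.08, 1.07 and 0.855). With mid DOX they were PTPRQ (7.67 ± 0.57), CGA (6.0 ± 0.47), TRHDE (5.82 ± 0.54), TMEFF2 (5.54 ± 0.54), PCK1 (5.51 ± 0.51) and SLITRK6 (5.11 ± 0.42). NMRAL1 was listed at 0 in the early DOX libraries and at 113, 53.7 and 144 in vehicle. The other early falls were SH3TC2 (-2.50 ± 0.46), PCOLCE2 (-2.44 ± 0.60), SCUBE1 (-2.19 ± 0.52), ADGRG6 (-2.16 ± 0.50), MYOM1 (-1.91 ± 0.44), MFGE8 (-1.79 ± 0.40) and ALDH1L1 (-1.77 ± 0.40). The mid falls were the lipocalins APOD (-2.69 ± 0.60) and LCN2 (-2.60 ± 0.55), the kinase CDKL1 (-2.41 ± 0.42), CCL2 (-1.96 ± 0.44), USP2 (-1.38 ± 0.31), GCH1 (-1.37 ± 0.32), KIAA0040 (-1.35 ± 0.31) and ACSL1 (-1.29 ± 0.27). NFATC2, COL2A1, ACAN and SOX9 lay between -0.74 and -0.03 at both times, and none passed (adjusted p 0.837 to 0.991).

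By list, early DOX in TGF-beta had 2 of 12 BMP targets up (ATOH8 1.06, SMAD9 0.98; camera adjusted p = 5.7e-04, adjusted p = 0.0815 with an estimated correlation). Of 13 WNT genes 1 was up (SFRP2 2.03; 5.7e-04, adjusted p = 0.0815 with an estimated correlation). Of 18 catabolic genes 3 were up (ADAMTS5 2.32, the collagenase MMP13 2.02, PTGS2 1.86; 0.0073, adjusted p = 0.286 with an estimated correlation). Of 12 interferon genes 1 was up (IFI44L 2.18; 0.00913, adjusted p = 0.525 with an estimated correlation), as was 1 of 6 adipocyte genes (PPARG 1.27; 0.0133, adjusted p = 0.0815 with an estimated correlation). MMP13, DLX5 (2.23), PDE4B (1.66) and, of 11 NFAT targets, PTGS2 and RCAN1 (1.32) were the genes up in the hypertrophic, osteoblast, CREB and NFAT lists. Adjusted over the list alone 3 BMP targets, 4 WNT, 5 catabolic, 3 interferon, 2 adipocyte and 2 articular genes rose. With mid DOX, ATOH8 (1.03; BMP targets 0.00565, adjusted p = 0.172 with an estimated correlation), SFRP2 (1.49; WNT 0.00696, adjusted p = 0.172 with an estimated correlation), DLX5 (1.60) and PPARG (1.53) were up. So was IFI44L (1.94; interferon 0.00169, adjusted p = 0.345 with an estimated correlation). Of 20 proliferation genes 1, TOP2A, rose (1.60) and the list was higher as a set (2.2e-04, adjusted p = 0.0484 with an estimated correlation). CCL2 and PDE4D (-1.17) fell among catabolic genes and CREB targets. Hypoxia genes were lower as a set (3.8e-04, adjusted p = 0.172 with an estimated correlation). Adjusted over the list alone 2 proliferation, 5 WNT, 2 interferon and 2 BMP target genes rose and 3 hypoxia genes fell with mid DOX.

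In articular, cartilage matrix, fibroblast, TGF-beta target and hypoxia lists 0 genes passed limma at either time in TGF-beta. At an unadjusted p under 0.05 they held 3, 1, 1, 1 and 2 genes with early DOX and 3, 0, 1, 2 and 6 with mid DOX. In each edgeR called 0, and DESeq2 called 2, 0, 1, 0 and 1 with early DOX and 2, 0, 0, 1 and 1 with mid DOX. The count of 259 moved to 157 and 148 without early DOX libraries 1 and 3 and to 161 and 172 without vehicle libraries 1 and 2. The count of 167 moved to 89 and 103 without mid DOX libraries 1 and 2 and to 111 and 110 without vehicle libraries 1 and 2. Of the named genes, 15 of 28 with early DOX and 11 of 24 with mid DOX lost their call without some library (7 to 13 and 3 to 11 per library left out). With early DOX PRG4 passed with DESeq2 (adjusted p = 0.00403, range 0.00403 to 0.248 over the alternatives), quantile normalization (0.00741) and a replicate block within each arm (0.00957). With mid DOX it passed with the same 3 alternatives (0.0124, 0.0108 and 0.0263, range 0.0108 to 0.411). A replicate block over both arms gave 0.137 and 0.276. With early DOX PRG4 also passed without early DOX library 2 (0.0447) or vehicle library 1 (0.0496).

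Mid and early DOX were compared directly, since both shared vehicle libraries. In BMP4 28 genes differed, 22 higher and 6 lower with mid DOX (26 and 14 with quantile normalization). With a replicate block 9 differed and with DESeq2 178. Among the genes higher with mid DOX were the neurotrophic factor receptor GFRA1, 2039 ± 179 against 492 ± 42.0 (2.05 ± 0.25, adjusted p = 0.00289), and the matrix protein RELN, 1183 ± 257 against 205 ± 98.9 (2.62 ± 0.40). FGF10 (3.04 ± 0.53), CHODL (2.28 ± 0.43), GPR183 (2.07 ± 0.28), SOX11 (1.90 ± 0.30) and COL4A6 (1.68 ± 0.32) were also higher, and FAM83H was listed at 0 with early DOX and at 199.9, 247.8 and 100.9 with mid DOX. DDIT4 (-1.69 ± 0.28), the embryonic myosin MYH3 (-1.62 ± 0.31), BNIP3 (-1.28 ± 0.18) and VLDLR (-1.22 ± 0.19) were lower. CREB5 was 2292 ± 605 with mid and 983 ± 67.8 with early DOX (1.19 ± 0.23, adjusted p = 0.0425), a call lost with quantile normalization (adjusted p = 0.0633, range 2.6e-04 to 0.188 over the alternatives), with a replicate block (0.151), with a block within each arm (0.105) and with only the groups compared (0.0891). The call was also lost in each fit that left out 1 of the 6 libraries. PRG4 did not pass (2.05 ± 0.43, adjusted p = 0.0738), but passed with quantile normalization (adjusted p = 0.018, range 4.6e-04 to 0.296 over the alternatives), a pseudocount of 8 (0.0482), a replicate block within each arm (0.0276) and DESeq2 (4.6e-04). As a set, hypoxia genes were lower with mid DOX (7 of 11 adjusted over the list alone, camera adjusted p = 3.3e-13, adjusted p = 0.0133 with an estimated correlation). So were stress response genes (4 adjusted over the list alone, 1.4e-08, adjusted p = 0.187 with an estimated correlation) and hedgehog genes (0.0292, adjusted p = 0.191 with an estimated correlation). Articular (0.00332, adjusted p = 0.191 with an estimated correlation), catabolic (0.00116, adjusted p = 0.191 with an estimated correlation) and fibroblast genes (0.026, adjusted p = 0.622 with an estimated correlation) were higher as sets. In these 3 lists and in hedgehog genes 0 single genes passed limma, with 4, 5, 2 and 2 at an unadjusted p under 0.05, 0 by edgeR and 2, 0, 2 and 1 by DESeq2. The 28 moved to 12 and 7 without early DOX libraries 1 and 2 and to 13, 10 and 10 without mid DOX libraries 1, 2 and 3. In all, 9 of 13 named genes lost their call without some library (4 to 9 per library left out).

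In TGF-beta 3 genes differed between mid and early DOX, named here after their values were seen. The zinc finger gene ZNF100 was lower (1.49 against 82.1, -5.52 ± 0.66, adjusted p = 0.00407), and HLA-DMA and CRIP3 were listed at 0 with early DOX and had means of 49.5 and 29.3 with mid DOX (adjusted p = 0.00772 and 0.0281). The count was 0 with edgeR, 1 with a replicate block and 47 with DESeq2, and 851 genes had an unadjusted p under 0.05. It was 1 without early DOX library 1 and 0 without early DOX library 2. HLA-DMA lies in the MHC region of chromosome 6, which held 20 of 151 placed genes listed at 0 in some libraries of a group and at 100 or more in another library of it (13.2%, against 0.602% of other genes that reach 100). CREB5 (-0.14 ± 0.23) and PRG4 (-0.18 ± 0.43) did not pass (adjusted p = 1 for both). Proliferation genes were higher as a set with mid DOX (9.8e-05, adjusted p = 0.0422 with an estimated correlation) and catabolic genes lower (1.8e-07, adjusted p = 0.0422 with an estimated correlation). Lists of CREB targets (0.00247, adjusted p = 0.279 with an estimated correlation), NFAT targets (0.00481, adjusted p = 0.555 with an estimated correlation) and hypoxia genes (0.00481, adjusted p = 0.332 with an estimated correlation) were lower. No single gene of these 5 lists passed limma or edgeR, while 4, 7, 2, 1 and 0 had an unadjusted p under 0.05 and DESeq2 called 1, 0, 0, 0 and 0.

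Whether the DOX effect differed between the arms was tested as the effect in TGF-beta minus that in BMP4. The early effect differed for 102 genes, 87 more positive in TGF-beta, and the mid effect for 28 genes, 16 more positive in TGF-beta. With a replicate block these counts were 34 and 4, and with DESeq2 351 and 278. FST, which encodes the activin antagonist follistatin, rose with mid DOX in TGF-beta to 1170 ± 221 from 186 ± 18 (2.63) and did not pass in BMP4 (-0.96), a difference of 3.60 ± 0.45 (adjusted p = 0.0035). FGF2 rose with mid DOX in BMP4 and stayed at 1780 ± 522 in TGF-beta (difference -6.98 ± 1.25, adjusted p = 0.0306). CXCL13 fell with mid DOX in BMP4 (-2.30) and not in TGF-beta (0.37), a difference of 2.67 ± 0.41. HOMER2 (3.03 ± 0.38), EFNA3 (2.41 ± 0.37), PCSK1N (-3.97 ± 0.68), DNAH17 (-3.64 ± 0.70) and CDKL1 (-3.19 ± 0.59) completed the named mid differences. Early differences were HS6ST2, a heparan sulfate sulfotransferase (5.65 ± 0.76), HCN3 (5.29 ± 1.16), MYOM1 (-2.93 ± 0.63), STAC2 (-2.56 ± 0.54), ZNF420 (-2.48 ± 0.51) and ZNF616 (-1.99 ± 0.43), together with FAM83H and KRTAP3-2, which involve groups listed at 0. For PRG4 the mid difference was -2.00 ± 0.61 (adjusted p = 0.223) and for COL10A1 1.22 ± 0.46 (adjusted p = 0.369). The early difference of CREB5 was 1.21 ± 0.32 (adjusted p = 0.108) and that of COL10A1 1.42 ± 0.46 (adjusted p = 0.224), and none of these 4 passed with limma. The early difference of CREB5 passed with DESeq2 (adjusted p = 0.0257, range 0.0257 to 0.257 over the alternatives).

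By list, the effect on BMP targets was more positive in TGF-beta at both times, with ATOH8 past the threshold (early 1.98, mid 2.11). Adjusted over the list alone 5 and 3 genes passed (camera adjusted p = 2.6e-07 and 1.4e-05, adjusted p = 0.0228 and 0.0365 with an estimated correlation). Proliferation genes did so with mid DOX (3 genes adjusted over the list alone, 2.5e-06, adjusted p = 0.0122 with an estimated correlation). DLX5 (early 2.57, mid 2.24) and SFRP2 (early 2.65) also passed. The early effect on hypertrophic genes (0.0085, adjusted p = 0.622 with an estimated correlation, and 0.0562 with quantile normalization) and catabolic genes (0.0418, adjusted p = 0.555 with an estimated correlation) was more positive in TGF-beta. That on hypoxia genes was more negative (0.013, adjusted p = 0.555 with an estimated correlation). The mid effect was more positive for hypertrophic (2.3e-04, adjusted p = 0.558 with an estimated correlation) and stress response genes (0.00483, adjusted p = 0.558 with an estimated correlation). It was more negative for articular (2.4e-04, adjusted p = 0.143 with an estimated correlation), fibroblast (3.6e-04, adjusted p = 0.401 with an estimated correlation) and catabolic genes (0.00483, adjusted p = 0.397 with an estimated correlation). The 102 moved to 50 without BMP4 early DOX library 3, 53 and 55 without BMP4 vehicle libraries 2 and 3, 66 and 52 without TGF-beta early DOX libraries 1 and 3 and 62 without TGF-beta vehicle library 2. The 28 moved to 14 and 8 without BMP4 mid DOX libraries 1 and 2, 9 and 9 without BMP4 vehicle libraries 2 and 3, 13 and 13 without TGF-beta mid DOX libraries 2 and 3 and 18 and 11 without TGF-beta vehicle libraries 1 and 2. Of the named genes, 6 of 11 early and 8 of 10 mid differences lost their call without some library (4 to 6 and 2 to 7 per library left out).

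The growth factor difference of each set served as a signature for the other set, so that no library was shared, although the lists were chosen on samples of this series. Genes over 2-fold higher in TGF-beta in the authors' deposited table (1947 tested) had a mean log2FC 1.46 above that of other genes in the CREB5 set's own TGF-beta against BMP4 comparison, and the BMP4-high genes (1631 tested) 2.12 below (-2.12). With mid DOX in BMP4 in the CREB5 set the TGF-beta-high genes were shifted by 0.43 (camera p = 5.4e-16, p = 0.00629 with an estimated correlation), with 113 members up and 0 down. The BMP4-high genes were shifted by -0.48 (2.0e-13, p = 8.1e-04 with an estimated correlation), with 6 up and 67 down. With early DOX the shifts were 0.35 (5.6e-11, p = 0.0203 with an estimated correlation) and -0.60 (1.6e-19, p = 1.4e-04 with an estimated correlation). In TGF-beta the shifts were 0.06 and 0.02 with early DOX and -0.03 and -0.02 with mid DOX, and none passed (camera p 0.098 to 0.974). The 0.06 became 0.084 with quantile normalization, 0.141 without early DOX library 2 and 0.088 without TGF-beta vehicle library 2, each passing camera. Without early DOX library 1 it was -0.028. The difference of the effects between arms passed for the BMP4-high genes (early 0.62, mid 0.46) and for the TGF-beta-high genes with mid DOX (-0.46, 2.3e-11, p = 0.0184 with an estimated correlation). For those with early DOX it was -0.29 (3.4e-05, p = 0.117 with an estimated correlation). With mid DOX in the NFATC2 set, the CREB5 set's TGF-beta-high genes (927 tested) shifted by 0.19 (1.0e-09, p = 0.00706 with an estimated correlation). Its BMP4-high genes (1418 tested) shifted by -0.16 (1.4e-06, p = 0.059 with an estimated correlation).

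**Figure D3:**
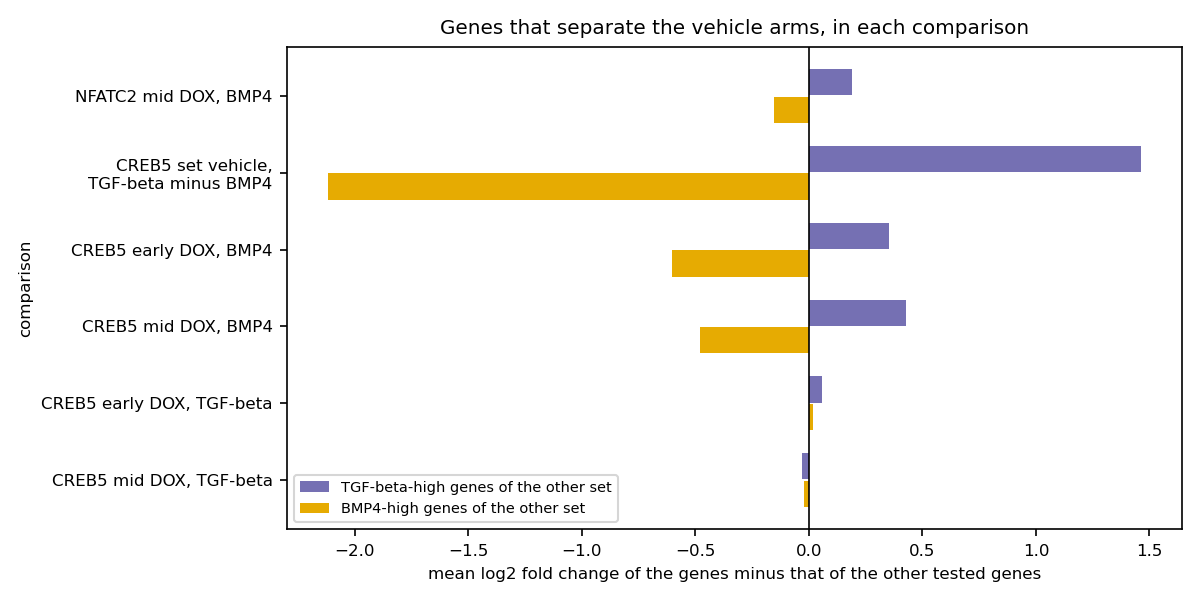
Bars from 0 show the mean log2 fold change of the TGF-beta-high and BMP4-high signature genes minus that of the other tested genes in 6 comparisons (3 libraries per group). The shifts are 0.43 and -0.48 with mid DOX in the CREB5 set in BMP4 and -0.03 and -0.02 in TGF-beta.

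Calls were also compared between comparisons that share no library, across genes, which are not independent replicates. Of the genes that rose with early DOX in the CREB5 set, 58 rose in both arms, where 2.38 would overlap if the lists were independent, 0 fell in both (0.415 if independent) and 8 had opposite calls. With mid DOX, 71 rose in both (2.24 if independent) 3 fell in both (0.189 if independent) and 1 had opposite calls. Between NFATC2 and CREB5 mid DOX in BMP4, 15 genes rose in both (6.22 if independent), among them the C-type natriuretic peptide gene NPPC (4.23 and 4.09), the activin subunit INHBA (1.79 and 2.47), TNC and PTGS2. In the same comparison 34 fell in both (2.11 if independent), among them COL10A1, IBSP, CXCL13 (-0.57 and -2.30) and ID2, and 2 had opposite calls. For 28 of these 34, with a mean of at least 50 in TGF-beta vehicle, the median log2FC with CREB5 mid DOX was -1.16 in BMP4 and -0.23 in TGF-beta and that with NFATC2 mid DOX in BMP4 -0.418, and 32 of the 34 were higher in BMP4 in the authors' deposited table. No sample had DOX without an induced gene. Between the authors' deposited table and the CREB5 set's TGF-beta against BMP4 comparison, 1316 genes were higher in TGF-beta in both (670 if independent), 1549 higher in BMP4 in both (777 if independent) and 33 opposite.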

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

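The tests chosen only after the result was seen were the relabellings of the 2 counts of genes and the splits of the 6 libraries; the relabellings of the signature differences were set out before their outcome was known. Results are given here because the DOX effect differed between the BMP4 and TGF-beta arms of the CREB5 set by a test of the difference itself (limma, adjusted p under 0.05, 12 libraries in 4 groups of 3).

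The early DOX effect differed between arms for 102 genes, and the highest of 99 other relabellings of the residuals gave 1, a share of 1 in 100. The relabelling ignores the replicate number, over which deviations in this set largely cancelled (variance ratio 0.122). It therefore cannot exclude chance. With the replicate block the count was 34. Without 1 library it was 50 to 97, with 50 without BMP4 early DOX library 3, 53 and 55 without BMP4 vehicle libraries 2 and 3, 66 and 52 without TGF-beta early DOX libraries 1 and 3 and 62 without TGF-beta vehicle library 2. FAM83H (9.512 as fitted) was listed at 0 in the 3 BMP4 early DOX libraries, with 281, 289 and 513 in vehicle. KRTAP3-2 (8.447 as fitted) was listed at 0 in the 3 TGF-beta vehicle libraries. Neither fitted value is a bound or a fold. HS6ST2 differed by 5.65, with -0.95 in BMP4 (adjusted p = 0.453) and 4.70 in TGF-beta (adjusted p = 5.6e-05). HCN3 differed by 5.291, with -0.78 (adjusted p = 0.738) and 4.51 (adjusted p = 0.00656). MYOM1 differed by -2.926, with 1.02 in BMP4 (adjusted p = 0.291) and -1.91 in TGF-beta (adjusted p = 0.0357). STAC2 differed by -2.555, with 1.21 (adjusted p = 0.119) and -1.34 (adjusted p = 0.117). ZNF420 differed by -2.481, with 1.84 (adjusted p = 0.0126) and -0.64 (adjusted p = 0.631). ZNF616 differed by -1.993, with 1.3 (adjusted p = 0.0317) and -0.69 (adjusted p = 0.433).

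The mid DOX effect differed for 28 genes, and the highest of 99 other relabellings gave 1, a share of 1 in 100. This relabelling has the same limit, so it cannot exclude chance. With the replicate block the count was 4. Without 1 library it was 8 to 25, with 14 and 8 without BMP4 mid DOX libraries 1 and 2, 9 and 9 without BMP4 vehicle libraries 2 and 3, 13 and 13 without TGF-beta mid DOX libraries 2 and 3 and 18 and 11 without TGF-beta vehicle libraries 1 and 2. FST differed by 3.596, with -0.96 in BMP4 (adjusted p = 0.149) and 2.63 in TGF-beta (adjusted p = 1.3e-04). HOMER2 differed by 3.032, with -0.78 (adjusted p = 0.169) and 2.25 (adjusted p = 1.2e-04). CXCL13 differed by 2.67, with -2.30 (adjusted p = 1.6e-04) and 0.37 (adjusted p = 0.753). EFNA3 differed by 2.405, with -2.10 (adjusted p = 1.6e-04) and 0.30 (adjusted p = 0.775). FGF2 differed by -6.975, with 6.84 (adjusted p = 2.1e-04) and -0.13 (adjusted p = 0.98). PCSK1N differed by -3.971, with 5.13 (adjusted p = 8.3e-06) and 1.16 (adjusted p = 0.401). DNAH17 differed by -3.635, with 3.92 (adjusted p = 1.6e-04) and 0.29 (adjusted p = 0.897). CDKL1 differed by -3.185, with 0.78 (adjusted p = 0.459) and -2.41 (adjusted p = 0.00565).

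For the signatures, the difference between arms of the TGF-beta-high genes with early DOX was -0.293, with 7 of 100 relabellings as large in size (highest other 0.419), so chance cannot be excluded. For the BMP4-high genes with early DOX it was 0.619 (highest other 0.526), with mid DOX the TGF-beta-high genes had -0.457 (highest other 0.426) and the BMP4-high genes 0.457 (highest other 0.389). In these 3 cases 1 of 100 relabellings, the real arrangement, was as large. The relabelling again ignores the replicate number, so it cannot exclude chance for these 3 either. By the choice of the lists, the vehicle levels of these genes differ between arms, which could by itself make the shifts differ.

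The comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. The counts, with the highest among the 9 other splits, were 802 and 1 for NFATC2 mid DOX, 3918 and 2 for TGF-beta against BMP4 vehicle, 345 and 0 for early and 349 and 2 for mid DOX in BMP4, 259 and 44 for early and 167 and 5 for mid DOX in TGF-beta, and 28 and 2 in BMP4 and 3 and 1 in TGF-beta for mid against early DOX. The signature values, TGF-beta-high then BMP4-high, each with the highest other size, were 0.191 (0.115) and -0.155 (0.07) for NFATC2 mid DOX, 1.464 (0.608) and -2.118 (0.79) for TGF-beta against BMP4 vehicle, 0.352 (0.276) and -0.602 (0.288) for early DOX in BMP4 and 0.426 (0.229) and -0.478 (0.251) for mid DOX in BMP4, and 1 of 10 splits was as large in each. In TGF-beta they were 0.059 (0.166) and 0.017 (0.156) with early and -0.031 (0.189) and -0.021 (0.113) with mid DOX, and 9 of 10 splits were as large in each.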

How the results depend on the processing

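The edgeR and DESeq2 tests, the block within each arm, the tests of signatures on the difference between arms and the alternatives for gene lists were chosen after seeing the data; the other alternatives were fixed before. Of 294 named gene calls, 3533 of 4298 values under alternatives kept the call, 765 lost it and 0 reversed. Of 56 named values that had not passed, 819 of 897 stayed, 19 passed and 59 reversed. Of 63 list calls, 63 held with a pseudocount of 8, 61 with quantile normalization, 63 with the replicate block and 8 with an estimated correlation, and 0 reversed. The planned count for TGF-beta against BMP4 vehicle in the NFATC2 set and its alternatives were not run, because the replicates in that table differed by less than counting noise. Depth was 16.8 to 24.0 M recovered reads. For CREB5 mid DOX in BMP4, 18.6% of simulated 2-fold changes were recovered, so such changes may often be missed. Unless a reason is given, the cause of a change below was not tested.

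By the rule set before, the replicate numbers were not treated as pairs: in the CREB5 set, correlations of deviations between same-numbered libraries were -0.273 to 0.33 within an arm and -0.48 to -0.05 between arms. No comparison had every pair over 0.1, and not every sample correlates best with its own number. An adjustment by number before deposit would itself lower these correlations, so they do not show that the numbers leave the samples unpaired. With the replicate block the counts were 196 (802 without) for NFATC2 mid DOX, 3135 (3918) for TGF-beta against BMP4 vehicle, 151 (345) for early and 179 (349) for mid DOX in BMP4, 160 (259) for early and 100 (167) for mid DOX in TGF-beta, 9 (28) and 1 (3) for mid against early DOX in BMP4 and TGF-beta, and 34 (102) and 4 (28) for the early and mid difference between arms. The block uses 2 residual degrees of freedom. With a block within each arm, mid against early DOX in TGF-beta gave 1 gene.

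With DESeq2 the counts were 1482 for NFATC2 mid DOX, 799 and 708 for early and mid DOX in BMP4, 472 and 373 in TGF-beta, 178 and 47 for mid against early DOX in BMP4 and TGF-beta, and 351 and 278 for the early and mid difference between arms. DESeq2 false calls on simulated data are given above. With edgeR, mid against early DOX in TGF-beta gave 0 genes (3 with limma, 851 at an unadjusted p under 0.05). With only the libraries of the groups compared, which leaves fewer libraries in the fit, the counts were 114 and 53 for early and mid DOX in TGF-beta, 3 and 0 for mid against early DOX in BMP4 and TGF-beta and 63 for the early difference between arms. For mid against early DOX in BMP4, a pseudocount of 8 gave 61, no filter 50, and quantile normalization 40, of which 26 higher. For mid against early DOX in TGF-beta, no filter gave 8 and the stricter filter 1.

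Leaving out 1 library gave 246 to 751 genes for NFATC2 mid DOX, 3080 to 3521 for TGF-beta against BMP4 vehicle, 81 to 288 for early and 153 to 287 for mid DOX in BMP4, 148 to 240 for early and 89 to 219 for mid DOX in TGF-beta, 7 to 23 and 0 to 3 for mid against early DOX in BMP4 and TGF-beta, and 50 to 97 and 8 to 25 for the early and mid difference between arms.

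Among signatures, the estimated correlation ended the calls of the BMP4-high genes with NFATC2 mid DOX (-0.155, p = 0.059) and of the TGF-beta-high genes in the early difference between arms (-0.293, p = 0.117). With early DOX in TGF-beta, quantile normalization gave 0.084 for the TGF-beta-high genes, which then passed camera, and -0.014 for the BMP4-high genes, which were -0.057 with no fold limit. Leaving out 1 library gave -0.028 to 0.141 (TGF-beta-high, passing camera without early DOX library 2, 0.141, and also without vehicle library 2) and -0.055 to 0.063 (BMP4-high) with early DOX in TGF-beta, and -0.119 to 0.046 and -0.093 to 0.024 with mid DOX.

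The following log2FC of genes that had not passed took the other sign. With quantile normalization these were SOX9 in TGF-beta against BMP4 vehicle (0.073), ACAN with early DOX in TGF-beta (0.126), NFATC2 (0.095), ACAN (0.27) and SOX9 (0.161) with mid DOX in TGF-beta, ACAN with mid against early DOX in TGF-beta (0.144) and COL2A1 in the early difference between arms (-0.014). COL2A1 with mid DOX in BMP4 was at 0 with quantile normalization. With edgeR and with DESeq2 the sign changed for ACAN with mid against early DOX in BMP4 (0.054) and ACAN (0.2) and SOX9 (-0.027) with mid against early DOX in TGF-beta. Leaving out 1 library gave CREB5 -0.609 to 0.332 with NFATC2 mid DOX and COL2A1 -1.232 to 0.143 with mid DOX in BMP4. With early DOX in TGF-beta it gave ACAN -0.701 to 0.334, NFATC2 -0.484 to 0.239, COL2A1 -1.372 to 0.334 and SOX9 -0.478 to 0.178, and with mid DOX NFATC2 -0.311 to 0.412, ACAN -0.724 to 0.465 and SOX9 -0.179 to 0.082. For mid against early DOX it gave ACAN -0.568 to 0.393 and COL2A1 -0.388 to 0.987 in BMP4, and in TGF-beta ACAN -0.54 to 0.588, SOX9 -0.218 to 0.438, NFATC2 -0.091 to 0.414, CREB5 -0.36 to 0.034, PRG4 -0.514 to 0.213 and COL2A1 -0.758 to 0.008. For the difference between arms it gave COL2A1 -0.528 to 1.178, PRG4 -0.064 to 0.624 and ACAN -0.232 to 0.803 with early DOX, and CREB5 -0.344 to 0.079, COL2A1 -1.147 to 0.559 and ACAN -0.174 to 1.015 with mid DOX.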

Other observations

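The tests chosen only after the result was seen were both tests of the deviations by replicate number, the test of the MHC region, the comparison with the NFATC2 median and the test of the BMP4-high genes; the test of the group labels and that of DOX in both arms were set out before their outcome was known.

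Deviations from the group means in the CREB5 set cancelled over the 6 libraries that share a replicate number. The variance of their sum was 0.122, 0.171 and 0.074 of the sum of their variances for the 3 numbers, and 1 of 1000 arrangements of the numbers within groups, the real one, had a mean ratio as low (0.122, lowest other 0.436, median 0.966). Opposite deviations of the BMP4 and TGF-beta libraries with no adjustment would need a correlation of 0.829 between same-numbered libraries of an arm, and the highest was 0.33, which argues against that. A candidate explanation is that values were adjusted for the number before deposit, which no source used here states, and whole reads do not argue against it, since some adjustments return whole numbers. If so, the fits without a block count too many residual degrees of freedom and their p-values may be too small. No biological explanation was tested. In the NFATC2 set in BMP4, same-numbered mid DOX and vehicle libraries also deviated in opposite directions (correlations -0.251, -0.468 and -0.476). The variance of their sum was 0.749, 0.535 and 0.527 of the sum of their variances. No arrangements were tried there, so the same doubt stays open for the 802 calls of NFATC2 mid DOX.

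In the CREB5 set 160 genes were listed at 0 in some libraries of a group and at 100 or more in another library of it. Of the 151 with a position, 20 lay in the MHC region (chromosome 6, 28 to 34 Mb), 13.2% against 0.602% of other genes that reach 100 (odds ratio 25.2, 95% interval 14.1 to 43.2, 2-sided Fisher's exact p = 8.3e-20). This is consistent with reads split among copies of these genes on alternate haplotypes of the reference, a hypothesis that a look at the reads would test. Growth factor or DOX also stays open: among MHC genes with both kinds of library, 41 groups mixed 0 and 100 or more, against a median of 49 when library labels were shuffled, and 17 of 1000 shuffles had as few. Of the changed genes in the 10 contrasts, 0 mixed 0 and 100 or more within a group compared. A gene with so wide a spread within a group could hardly pass, so this does not show that the calls are free of the pattern. PHLDA2, called between the vehicle arms, mixed both in 2 other groups. Genes listed at 0 in all libraries of a group, such as FAM83H with early DOX in BMP4, are not covered by the count.

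The 34 genes that fell with mid DOX in BMP4 for both NFATC2 and CREB5 were weighed against DOX itself. If DOX acted alike in both arms, the 28 genes with a mean of at least 50 in TGF-beta vehicle would have a median log2FC at or below -0.578 with CREB5 mid DOX in TGF-beta, which is 0.5 times their median in BMP4 (-1.156). The median was -0.227 (95% bootstrap interval -0.317 to 0.006). That bound was set too low, because the genes were chosen by their fall in the same BMP4 values, and an effect of DOX shared by both sets would have to be as small as the fall in the NFATC2 set. With NFATC2 mid DOX the median of these genes was -0.418, and 0.5 times that, -0.209, lies within the interval. Of the 28 genes, 19 were lower in TGF-beta, F2R past the threshold (-1.16, adjusted p = 0.00192). An effect of DOX, alike in both arms or in BMP4 alone, therefore stays open, and no control with DOX alone was among the samples. Of the 34 genes, 94.1% were BMP4-high in the authors' deposited table, against 22.9% of all genes tested in both (Fisher's exact p = 1.0e-18), which is consistent with a shift of both inductions away from BMP4-high genes. That table shares its BMP4 vehicle libraries with the NFATC2 comparison, so the share is not independent of it.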
